A study of Homo sapiens with 30 samples.

How the data were processed

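Total RNA from 30 skin samples was amplified and labelled with biotin using the Illumina TotalPrep kit, per the labels' protocols, and hybridised to Illumina bead arrays, whose type, scanner software and slide layout are not given in the sources used here. The biopsied region stated in the labels gave the groups, sclerotic (n = 12), inflammatory border (n = 8) and unaffected (n = 10). The titles of 2 samples, 1 sclerotic and 1 border, also carry an abbreviation that the labels do not explain, and a fit without them was run. The 30 titles open with 14 different numbers, each used at most once per group. The labels do not say what the number stands for or whether the samples of a group came from different people, so p-values measure the spread between these samples only.

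The authors deposited a table of probe signals, an intensity on a linear scale that was not normalised between arrays, together with a detection score per probe and array, per the file headers. The values show that a background had already been subtracted from the deposited signal, since 23.2% to 27.0% of the values per array lay below 0. The deposited detection score rose with the signal from 0 to 1 in steps and was read as 1 minus the detection p-value, the share of negative control probes that a probe exceeded. A second deposited table holds the authors' processed intensity values, which had the same quantiles on every array (medians 123.7 to 123.9, lowest value 86.8), so they are quantile-normalised on a linear scale and not centred. How the authors corrected their background is not given in the sources used here. Each column of that table had the ranks of the signal column of its own sample for 30 of 30 arrays, and it was used as an alternative source of values.

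The signal table held 45234 probes. 20 of its lines were damaged, or had signals whose rank differed from that in the authors' processed values by more than 0.2% of the probes, and were left out, which left 45214. Gene names came from the target column of the deposited table and were brought up to date with a list of RefSeq genes of assembly GRCh38.p14, used only for names. Of the probes, 26641 carried a current symbol, 4593 were given a newer one, 217 had a name that is an older symbol of several genes and kept it, and 11385 matched no current gene and kept the name in the table. Cluster names without a gene (2344 probes) and names turned into dates (54 probes) were left unnamed. The design names no genome build, so no coordinates are given. XIST, TSIX and Y-linked genes (144 probes) were left out of all tests because the samples are from patients.

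Signals were corrected with limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0) by its negative-control method, with the background estimated from the detection p-values, an offset of 16 and quantile normalisation, on the log2 scale. Probes with a detection p-value under 0.05 on at least 8 arrays were kept, 22362 of them with a gene name, and each gene was represented by its probe with the highest mean, which gave 16954 genes. The rule on probes matters where probes of a gene disagree, which was so for 2 of the 40 results past the test among named genes with more than 1 probe. One model with a mean per group was fitted to all 30 arrays (lmFit and eBayes with default settings), so that the groups shared 1 estimate of the spread. The contrasts were sclerotic minus unaffected, border minus unaffected, border minus sclerotic, and the mean of both lesional regions minus unaffected, and a gene passed at a Benjamini-Hochberg adjusted p-value under 0.05 with no minimum fold.

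Gene lists (32) for interferon responses, immune cells, matrix, signalling pathways, skin cell types and appendages, and general cell processes were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. Members were counted as higher or lower over all genes and again adjusted over the list alone. Some lists share members with each other or with other cells of skin, and none was chosen on these samples. The genes that could be named were the 8 largest rises and falls past the test in each of the first 3 contrasts, up to 4 members with the smallest p-value from each list that passed or held a gene past the test, and, in a contrast where fewer than 3 genes passed, the 3 with the smallest p-value in each direction. The text names a part of these, picked after their values were seen, and where a gene is named in several contrasts it was not always picked by the rule in each. Probes among the largest rises whose target has no current symbol are not named.

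The title number was used as a fixed block and as a random block (consensus correlation 0.286) in alternative fits. Over 21 pairs of arrays with the same number, the mean correlation of deviations from the group means was 0.352, against -0.053 for other pairs, and 18 of 27 arrays with a partner correlated best with 1 of their own number. Of the 21 pairs, 2 had a correlation of 0.1 or less (-0.124 and 0.067). In these fits and in counts of pairs the number was therefore treated as pairing samples. This reads it as standing for a person, which the labels do not state. The main fit had no block, so its standard errors and p-values, and the list tests on it, are unpaired. Blocked values are given for the numbers of genes, for list calls that a block changes, and where the results state that no member of a list passed and a block changes that. Other numbers of list members and other medians also change with a block, and those are not all given. The other alternatives were no background correction, normexp with an offset of 50, median scaling and cyclic loess, the authors' processed values, no filter or a stricter filter on dim probes, eBayes with trend and robust settings, array weights, subsets of samples, the most variable probe per gene, and leaving out each array in turn. The groups, tests, gene lists, naming rule and these alternatives were set before the data were examined. Fits without 2 arrays whose pairing was in doubt, fits by position in the deposited table, and list tests without single arrays were added later.

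The steps were tested on simulated data with the same arrays and 16954 genes, of which 100 were changed at each size. For sclerotic against unaffected skin 99% of the genes changed by 1 on the log2 scale were recovered, for border against unaffected skin 96%, for border against sclerotic skin 98% and for both lesional regions 99%, with 100% at a change of 2 in each. Of the genes called, 4.33%, 7.98%, 6.16% and 6.13% were false in these comparisons, against a nominal 5%. The simulated genes varied independently, with no correlation within title numbers and no difference by position in the deposited table. These shares therefore do not give the rate of false calls or the power on the real arrays. Counts of genes shared between comparisons with the same unaffected arrays were set against simulated unchanged groups and against splits of those arrays.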

Results

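Gene expression was measured on Illumina bead arrays in skin from people with morphea, an inflammatory disease in which patches of skin harden through deposition of collagen. The 30 arrays, each of total RNA from 1 sample, fell into 3 groups by the region that was biopsied, with 12 from sclerotic (hardened) skin, 8 from the inflammatory border of a lesion and 10 from unaffected skin. Between 19994 and 22349 probes, or 44.2% to 49.4%, were detected per array. The share was 47.0% ± 1.42 (SD, n = 10) on unaffected, 47.5% ± 1.18 (SD, n = 8) on border and 47.5% ± 1.29 (SD, n = 12) on sclerotic arrays. The upper quartile of the deposited signal before normalisation was 84.8 ± 13.2 (SD, n = 10) on unaffected arrays, against 97.7 ± 7.41 (SD, n = 8) on border and 95.6 ± 10.3 (SD, n = 12) on sclerotic arrays. The number of arrays limits the precision of every value. A number that opens each sample title occurred in both the sclerotic and the unaffected group 10 times, and in both the border and the unaffected group 5 times. Arrays that share such a number are called number-matched pairs.

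Sclerotic skin was first compared with unaffected skin, the contrast of the hardened region with skin outside the lesions. Interferon-induced, T cell and TGF-beta-responsive genes were higher in sclerotic skin (n = 12) than in unaffected skin (n = 10), and sweat gland genes were lower. These were list results of camera in limma at a preset correlation, and with an estimated correlation none passed (adjusted p = 0.21 for interferon-gamma-induced, 0.184 for type I interferon-induced, T cell and TGF-beta-responsive, and 0.219 for sweat gland genes). CXCL9, an interferon-gamma-induced chemokine that attracts T cells, rose 8.23-fold (log2 3.04, SE 0.77, higher in 9 of 10 number-matched pairs, adjusted p = 0.0208 in limma). COMP, a pentameric protein of the extracellular matrix, rose 8.75-fold (log2 3.13, SE 0.71, higher in 9 of 10 pairs, adjusted p = 0.0114 in limma). DCD, which encodes the sweat antimicrobial peptide dermcidin, was 26-fold lower (log2 -4.70, SE 1.14, lower in 7 of 10 pairs, adjusted p = 0.0166 in limma) and was detected on 7 of 12 sclerotic and 10 of 10 unaffected arrays. The SD of its log2 level was 3.73 on sclerotic and 1.11 on unaffected arrays, so this fold is a mean over unlike sclerotic arrays.

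**Figure D1:**
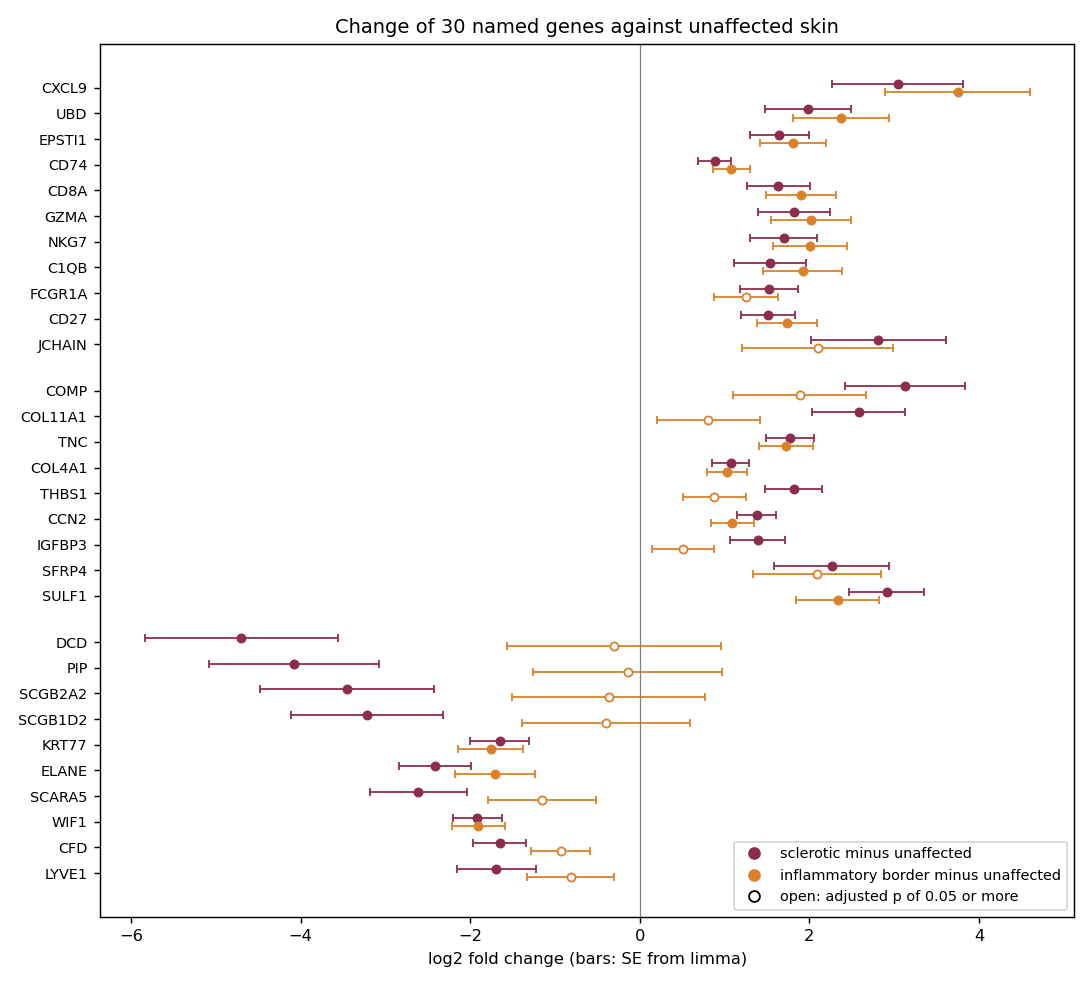
Log2 fold change against unaffected skin (x axis) of 30 named genes (y axis) in sclerotic skin (n = 12) and in the inflammatory border (n = 8), each against 10 unaffected arrays. Bars are standard errors from limma and open points have an adjusted p of 0.05 or more. CXCL9 lies at 3.04 in sclerotic and 3.75 in border skin, whereas DCD lies at -4.70 in sclerotic skin and its border value did not pass the test.

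The lists of the interferon response and of immune cells did not all move alike in sclerotic skin. Of 16 interferon-gamma-induced genes measured, 9 rose and none fell (13 rose when adjusted over the list alone). The interferon-gamma list had a median log2 change of 0.72 (camera adjusted p = 2e-10 in limma, and adjusted p = 0.21 with an estimated correlation). Among them UBD, a ubiquitin-like modifier, rose 3.96-fold (log2 1.99, SE 0.51) and IRF1 2.06-fold (log2 1.04, SE 0.28). Of 18 type I interferon-induced genes, 8 rose and none fell (16 rose adjusted over the list alone). The type I list had a median of 0.75 (camera adjusted p = 6.44e-13 in limma, and adjusted p = 0.184 with an estimated correlation). EPSTI1 rose 3.13-fold, OAS2 2.49-fold and IFI27 2.41-fold. MHC class II genes, which encode the antigen-presenting molecules and their chaperones, had 6 of 10 members higher (8 adjusted over the list alone) and a median of 0.86 (camera adjusted p = 1.92e-08 in limma, and adjusted p = 0.184 with an estimated correlation). The invariant chain CD74 rose 1.84-fold and HLA-DPA1 1.92-fold. Cytokines and chemokines had 7 of 31 members higher and 1 lower (11 and 2 adjusted over the list alone). This list had a median of 0.20 (camera adjusted p = 0.00272 in limma, and adjusted p = 0.359 with an estimated correlation). CCL5, a T cell attractant, rose 3.21-fold (log2 1.68, SE 0.42), CCL8 2.88-fold, CCL2, a monocyte attractant, 2.39-fold, and IL15 1.56-fold.

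Of 19 T cell markers, 10 rose and none fell (17 rose adjusted over the list alone). The T cell list had a median log2 change of 0.996 (camera adjusted p = 4.71e-14 in limma, and adjusted p = 0.184 with an estimated correlation), and its members include CD8A at 3.10-fold (log2 1.63, SE 0.37), CD2 at 2.55-fold and CD3G at 1.99-fold. Of 11 markers of cytotoxic and NK cells, 8 rose and none fell (10 rose adjusted over the list alone). The cytotoxic cell list had a median of 1.20 (camera adjusted p = 6.85e-11 in limma, and adjusted p = 0.184 with an estimated correlation). The granule proteases GZMA and GZMK rose 3.52-fold (log2 1.82, SE 0.42) and 3.54-fold (log2 1.82, SE 0.44). NKG7 rose 3.24-fold and KLRD1 2.30-fold, the latter detected on 4 of 10 unaffected arrays. Of 11 B and plasma cell markers, 2 rose (4 adjusted over the list alone). The B cell list had a median of 0.76 (camera adjusted p = 3.98e-06 in limma, and adjusted p = 0.223 with an estimated correlation), and of 0.42 without sclerotic array 8. The 2 genes were CD27, a receptor also found on T cells, at 2.86-fold (log2 1.51, SE 0.32) and JCHAIN, the joining chain of secreted antibodies, at 7.04-fold (log2 2.82, SE 0.80). IGLL1, an immunoglobulin lambda-like gene, had a log2 rise of 4.21 (SE 0.81, higher in 9 of 10 pairs, adjusted p = 0.00468 in limma). However, immunoglobulin genes hold near-identical copies and the specificity of its probe was not tested. Of 18 markers of macrophages and monocytes, 7 rose (15 adjusted over the list alone). The macrophage list had a median of 0.86 (camera adjusted p = 5.79e-11 in limma, and adjusted p = 0.184 with an estimated correlation). The complement subunit gene C1QB rose 2.90-fold (log2 1.54, SE 0.42), and the scavenger receptor MSR1 1.88-fold. The Fc receptor gene FCGR1A also passed, but was detected on only 1 of 10 unaffected arrays, so no fold is given. Among 15 markers of dendritic and Langerhans cells, CCR7, the lymph node homing receptor, rose 2.57-fold and the list had a median of 0.10 (camera adjusted p = 0.0666 in limma, and adjusted p = 0.0355 with the title number as a fixed block). None of 8 mast cell markers passed over all genes, although 5 were lower with the title number as a fixed block and 4 with it as a random block, and 5 were lower adjusted over the list alone. The mast cell list fell with a median of -0.41 (camera adjusted p = 0.00044 in limma, and adjusted p = 0.219 with an estimated correlation). KIT had a log2 change of -0.42 (SE 0.14) and HDC at -0.54 (SE 0.19).

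**Figure D2:**
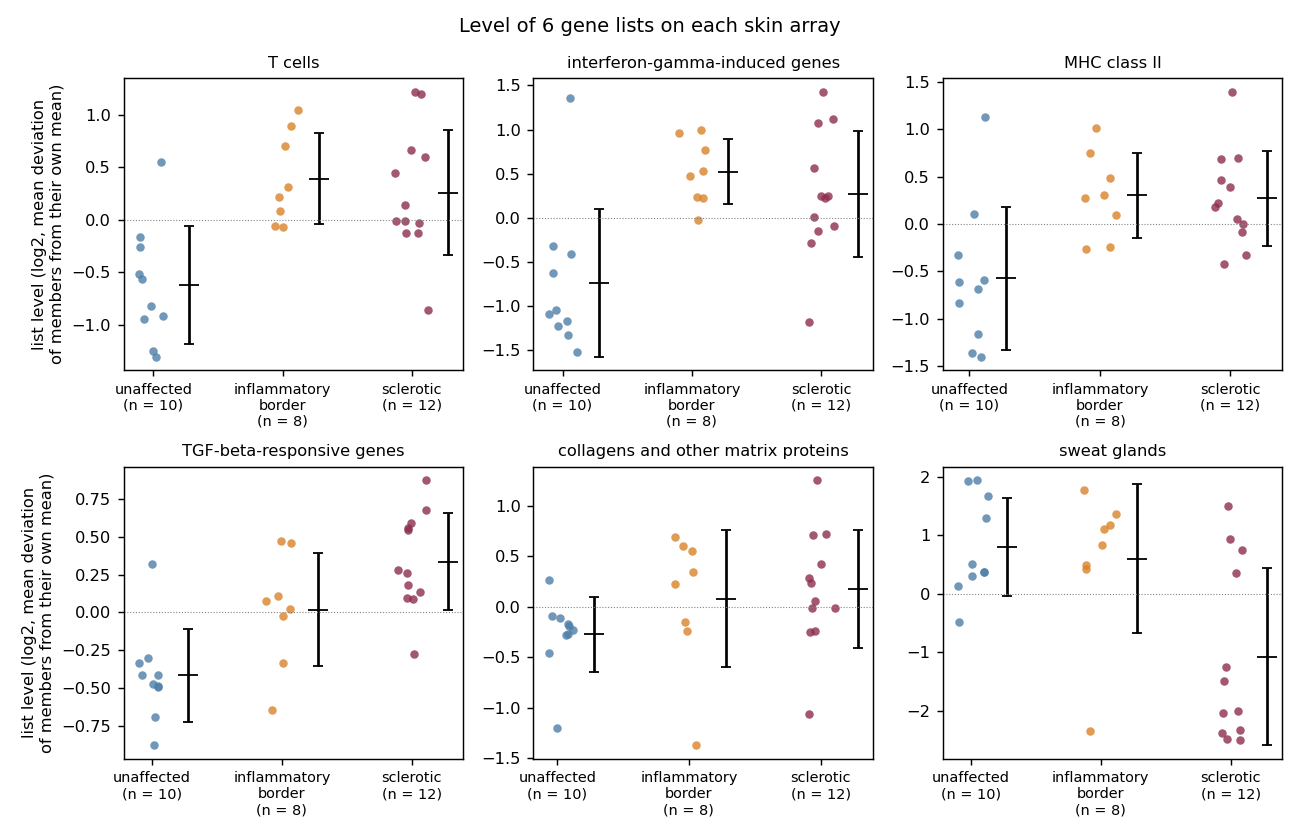
Level of 6 gene lists (y axis, mean log2 deviation of the members from their own mean over all arrays) on each array of unaffected (n = 10), inflammatory border (n = 8) and sclerotic skin (n = 12, x axis). Points are arrays, spread sideways only for legibility, and bars are the mean ± SD, which for sweat glands were 0.81 ± 0.84, 0.60 ± 1.27 and -1.08 ± 1.52.

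Genes of the connective tissue differed in part. Of 16 TGF-beta-responsive genes, 9 rose and none fell (10 rose adjusted over the list alone). The TGF-beta list had a median log2 change of 0.54 (camera adjusted p = 1.72e-08 in limma, and adjusted p = 0.184 with an estimated correlation). CCN2, a matricellular growth factor, rose 2.60-fold (log2 1.38, SE 0.23), THBS1, a thrombospondin that activates latent TGF-beta, 3.51-fold (log2 1.81, SE 0.34), and IGFBP3 2.62-fold (log2 1.39, SE 0.33). Of 36 collagens and other matrix proteins, 9 rose, 1 fell and 26 did not pass (13 rose and 2 fell adjusted over the list alone). The matrix list had a median of 0.17 (camera adjusted p = 0.000691 in limma, and adjusted p = 0.565 with an estimated correlation). This median was 0.07 without unaffected array 7, which stood apart, and 0.10, 0.10, 0.30 and 0.10 without sclerotic arrays 3, 4, 9 and 10. TNC, a matrix glycoprotein induced in wounds, rose 3.41-fold (log2 1.77, SE 0.29), and the basement membrane collagen chains COL4A1 and COL4A2 rose 2.11-fold and 1.72-fold. COL11A1, a fibrillar collagen gene, had a log2 change of 2.58 (SE 0.55), with unaffected skin near background (detected on 3 of 10 arrays). Of 16 Wnt pathway genes, 2 rose and 1 fell (5 and 3 adjusted over the list alone). The Wnt list did not pass (median 0.03, camera adjusted p = 0.628 in limma). The Wnt inhibitor WIF1 was 3.77-fold lower (log2 -1.92, SE 0.29, lower in 9 of 10 pairs, adjusted p = 0.00153 in limma) and was detected on 5 of 12 sclerotic arrays. By contrast, the secreted Wnt modulators SFRP4 and DKK3 rose 4.81-fold and 1.53-fold. Among 21 fibroblast markers 1 rose and 3 fell (4 and 6 adjusted over the list alone). The fibroblast list did not pass (median -0.27, camera adjusted p = 0.158 in limma). THY1 was 2.46-fold higher and TWIST1 had a log2 change of -0.73 (SE 0.20). The fibroblast markers CD34 (log2 -0.75, SE 0.18) and CXCL12 (log2 -0.92, SE 0.27) fell on the probe used. Of the other probes of each gene, 1 also had a negative change (-0.87 and -1.07) and 1 had a change of the opposite sign (0.04 and 0.08), the latter for CD34 near background.

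Of 17 endothelial markers 3 rose and 1 fell (4 and 1 adjusted over the list alone). The endothelial list had a median log2 change of 0.25 (camera adjusted p = 0.00662 in limma, and adjusted p = 0.4 with an estimated correlation). The endothelial genes PECAM1, PLVAP and VCAM1, the last an adhesion receptor for leukocytes, rose 1.46-fold, 1.48-fold and 2.22-fold. The lymphatic marker LYVE1 had a log2 change of -1.69 (SE 0.46, lower in 8 of 10 pairs, adjusted p = 0.0286 in limma). Of 14 markers of smooth muscle and pericytes, TAGLN rose 1.67-fold (2 rose adjusted over the list alone). The smooth muscle list had a median of 0.36 (camera adjusted p = 0.0103 in limma, and adjusted p = 0.53 with an estimated correlation), which did not pass without unaffected array 9 (0.33, adjusted p = 0.0587 in limma). Of 17 adipocyte markers, CFD, which encodes the complement factor adipsin, was 3.14-fold lower (log2 -1.65, SE 0.31) and no other passed. The adipocyte list had a median of -0.03 and a mean of 0.02 (camera adjusted p = 0.696 in limma). SCARA5 and CLEC3B, a scavenger receptor and a plasminogen-binding protein, were among the 8 largest falls at log2 changes of -2.61 (SE 0.57) and -2.22 (SE 0.45). So were the calcium channel gene CACNA1H at -2.12 (SE 0.51) and the neutrophil elastase gene ELANE at -2.42 (SE 0.42), the latter detected on 7 of 12 sclerotic arrays.

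Sweat gland genes fell in sclerotic skin on average, with 6 of 13 lower and none higher (10 lower adjusted over the list alone). The fall was not shared by all sclerotic arrays. Arrays 1, 2, 4 and 11 had list levels of 1.51, 0.74, 0.36 and 0.95, within the unaffected range of -0.48 to 1.94. Every other sclerotic array lay below that range, at -2.50 to -1.25. The sweat gland list had a median log2 change of -1.41 (camera adjusted p = 1.92e-08 in limma, and adjusted p = 0.219 with an estimated correlation). PIP, a secretory glycoprotein, was 16.9-fold lower (log2 -4.08, SE 1.01) and was detected on 6 of 12 sclerotic arrays. SCGB1D2, a secretoglobin, was 9.30-fold lower (log2 -3.22, SE 0.89) and detected on 9 of 12, and the keratin KRT77 was 3.15-fold lower (log2 -1.65, SE 0.35). Leaving out 1 sclerotic array at a time gave a median between -1.33 and -1.61 and between 3 and 8 members lower. Without sclerotic array 3, 5, 7 or 10 the number lower was 3. Of 8 sebaceous gland genes, PM20D1 fell by 1.47 on the log2 scale (SE 0.43). The sebaceous gland list had a median of -0.38 (camera adjusted p = 0.00579 in limma, and adjusted p = 0.443 with an estimated correlation). Unaffected array 4 stood apart for this list, and without it the median was -0.14 (adjusted p = 0.0391 in limma). Of 12 hair follicle genes, the hair keratin KRT31 fell by 0.51 on the log2 scale (SE 0.13), and the list did not pass (median -0.19, camera adjusted p = 0.34 in limma).

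Of 16 genes of inflamed keratinocytes, S100A9, a subunit of calprotectin, rose 4.90-fold (log2 2.29, SE 0.67), and 3 rose adjusted over the list alone. The inflamed keratinocyte list had a median log2 change of 0.74 (camera adjusted p = 0.00272 in limma, and adjusted p = 0.53 with an estimated correlation). None of 26 genes of differentiating keratinocytes and the cornified envelope passed (2 were lower with the title number as a random block). Their list fell with a median of -0.19 (camera adjusted p = 0.00654 in limma, and adjusted p = 0.632 with an estimated correlation). It had a median of -0.11 without sclerotic array 3 and did not pass without sclerotic array 8 (-0.12, adjusted p = 0.08 in limma). SPRR2G, which encodes a small proline-rich protein of the cornified envelope and is in none of these lists, rose 8.47-fold (log2 3.08, SE 0.70, higher in 8 of 10 pairs, adjusted p = 0.0115 in limma). None of 17 proliferation genes passed (1 was higher with that random block), although the list rose with a median of 0.20 (camera adjusted p = 0.00486 in limma, and adjusted p = 0.58 with an estimated correlation). It did not pass without sclerotic array 5 or 6 (0.12 and 0.11, adjusted p = 0.054 and 0.0589 in limma), and had a median of 0.13 without sclerotic array 9. Of 25 ribosomal protein genes 2 fell (3 adjusted over the list alone). The ribosomal list had a median of -0.07 (camera adjusted p = 0.000918 in limma, and adjusted p = 0.299 with an estimated correlation). Under median scaling the median was 0.02 while the test still gave a lower direction. None of 21 oxidative phosphorylation genes passed. That list fell with a median of -0.07 (camera adjusted p = 0.0126 in limma, and adjusted p = 0.476 with an estimated correlation), a direction that turned to 0.09 under median scaling.

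No member of 7 further lists passed over all genes in sclerotic skin, and the lists themselves did not pass in camera. With the title number as a fixed block 1 basal keratinocyte gene and 1 immediate early gene were higher, and under each block 1 nerve gene was lower. The median log2 changes of the lists were 0.06 for basal keratinocytes (adjusted p = 0.89 in limma), 0.04 for melanocytes (adjusted p = 0.969), -0.04 for Schwann cells and nerve (adjusted p = 0.464), -0.02 for skeletal muscle (adjusted p = 0.821), 0.01 for red blood cells (adjusted p = 0.969), 0.17 for immediate early genes (adjusted p = 0.115, and adjusted p = 0.03 with the title number as a fixed block) and -0.02 for heat shock genes (adjusted p = 0.805). For adipocytes, basal keratinocytes, melanocytes, skeletal muscle and red blood cells the median, the mean and the direction of the test did not share 1 sign.

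In the limma fit of 16954 genes, 919 differed between sclerotic and unaffected skin at an adjusted p under 0.05, with 529 higher and 390 lower, of which 153 and 82 changed at least 2-fold. With the title number as a fixed block the count was 1866 (956 higher, 910 lower), and with it as a random block 2077 (1105 higher, 972 lower). Without filtering dim probes it was 566, using only numbers present in both groups 433, and without the 2 arrays of 1 number whose pairing was in doubt 1903. Arrays also differed by their position in the deposited table. The count was 1110 with 3 stretches of that order as a block, 194 within the first 12 arrays and 0 within the last 18, where 1989 genes had an unadjusted p under 0.05 in limma. Median scaling in place of quantile normalisation moved the median of all genes from -0.01 to 0.11 and the share higher among the genes called from 57.6% to 88.5%. Leaving out 1 array at a time gave 530 (without sclerotic array 10) to 1679 (without unaffected array 9), with 534 and 591 without unaffected arrays 4 and 6 and 603 without sclerotic array 9.

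The inflammatory border was compared with unaffected skin to describe the active edge of a lesion. Interferon-induced genes, T cell and cytotoxic cell genes were higher in border skin (n = 8) than in unaffected skin (n = 10). These too were list results of camera in limma, with adjusted p = 0.0927 for each with an estimated correlation. CXCL9 rose 13.4-fold (log2 3.75, SE 0.86, higher in 5 of 5 pairs, adjusted p = 0.0258 in limma) and CXCL10, a chemokine with the same receptor, 8.50-fold (log2 3.09, SE 0.76, 5 of 5 pairs, adjusted p = 0.0312 in limma). GZMB, a cytotoxic granule protease, rose 4.39-fold (log2 2.13, SE 0.48, 5 of 5 pairs, adjusted p = 0.0254 in limma), detected on 6 of 10 unaffected arrays. WIF1 was 3.74-fold lower (log2 -1.90, SE 0.32, lower in 5 of 5 pairs, adjusted p = 0.0228 in limma), detected on 6 of 8 border arrays. No gene passed in limma with the title number as a fixed block (adjusted p = 0.062 for each of these 4). Each call over all genes given here for a gene or a list member in border skin is thus lost with that block. Calls adjusted over a list alone were not computed with it. All 51 calls of named genes in border skin held with it as a random block.

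Of 16 interferon-gamma-induced genes 11 rose in border skin (13 adjusted over the list alone). Their median log2 change was 0.89 (camera adjusted p = 1.21e-14 in limma, and adjusted p = 0.0927 with an estimated correlation), and UBD rose 5.18-fold. Of 18 type I interferon-induced genes 6 rose (16 adjusted over the list alone). These genes had a median of 0.84 (camera adjusted p = 3.84e-15 in limma, and adjusted p = 0.0927 with an estimated correlation), including EPSTI1 at 3.50-fold and OAS2 at 2.73-fold. Of 10 MHC class II genes 7 rose (8 adjusted over the list alone). The class II list had a median of 1.08 (camera adjusted p = 3.97e-10 in limma, and adjusted p = 0.0927 with an estimated correlation), among them CD74 at 2.12-fold and HLA-DMB at 2.22-fold. Of 31 cytokines and chemokines 4 rose (10 rose and 1 fell adjusted over the list alone). The cytokine list had a median of 0.23 (camera adjusted p = 0.000177 in limma, and adjusted p = 0.238 with an estimated correlation), or 0.35 with the title number as a fixed block. CCL5 rose 4.06-fold and IL15 1.84-fold. Of 19 T cell markers 9 rose (17 adjusted over the list alone). T cell markers had a median of 1.16 (camera adjusted p = 1.05e-16 in limma, and adjusted p = 0.0927 with an estimated correlation), such as CD8A at 3.74-fold and CD2 at 3.02-fold. Of 11 cytotoxic and NK cell markers 6 rose (11 adjusted over the list alone). Cytotoxic cell markers had a median of 1.19 (camera adjusted p = 1.06e-12 in limma, and adjusted p = 0.0927 with an estimated correlation), such as NKG7 at 4.02-fold and GZMA at 4.05-fold. Of 18 macrophage and monocyte markers 6 rose (16 adjusted over the list alone). Macrophage markers had a median of 1.10 (camera adjusted p = 7.13e-15 in limma, and adjusted p = 0.0927 with an estimated correlation), such as C1QB at 3.79-fold and the lysosomal protein gene CD68 at 2.16-fold. ADAMDEC1, a metalloprotease gene of macrophages and dendritic cells outside these lists, rose 6.31-fold (log2 2.66, SE 0.54) and was detected on 7 of 10 unaffected arrays.

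Among B and plasma cell markers, CD27 rose 3.34-fold and JCHAIN did not pass (log2 2.10, SE 0.89). The list median was 0.45 (camera adjusted p = 0.00108 in limma, and adjusted p = 0.405 with an estimated correlation), and 0.20 without border array 3. IGLL1 had a log2 rise of 3.42 (SE 0.90), with the same limit on its probe as above. No dendritic or Langerhans cell marker passed (2 rose with the title number as a random block), and the list median was 0.23 (camera adjusted p = 0.039 in limma, and adjusted p = 0.646 with an estimated correlation). That list did not pass without border array 1, 4, 6 or 8 (adjusted p = 0.0927, 0.108, 0.41 and 0.0755 in limma, with a median of 0.11 without array 6). Nor did it without unaffected array 2, 4 or 7 (adjusted p = 0.163, 0.103 and 0.0932 in limma, with a median of 0.14 without array 2). Likewise no mast cell marker passed (1 fell with that random block), with a list median of -0.30 (camera adjusted p = 0.016 in limma, and adjusted p = 0.405 with an estimated correlation), which did not pass without border array 3 (-0.22, adjusted p = 0.0809 in limma). Of 36 collagens and other matrix proteins, TNC and COL4A1 rose 3.31-fold and 2.04-fold (4 rose adjusted over the list alone). Matrix genes had a median of 0.26 (camera adjusted p = 0.000921 in limma, and adjusted p = 0.617 with an estimated correlation), of 0.12 without border array 1 and of 0.48 without border array 7. Of 16 TGF-beta-responsive genes, CCN2 rose 2.13-fold (4 rose and 1 fell adjusted over the list alone). TGF-beta-responsive genes had a median of 0.29 (camera adjusted p = 0.00108 in limma, and adjusted p = 0.305 with an estimated correlation). SULF1, an enzyme that edits heparan sulfate, rose 5.04-fold (log2 2.33, SE 0.49), and LCE3D, a late cornified envelope gene, 4.36-fold (log2 2.12, SE 0.59). Of 17 endothelial markers 2 rose (8 adjusted over the list alone), PECAM1 by 1.57-fold and VWF, the von Willebrand factor gene, by 1.59-fold. Endothelial markers had a median of 0.36 (camera adjusted p = 4.72e-06 in limma, and adjusted p = 0.0927 with an estimated correlation). TAGLN was the 1 of 14 smooth muscle and pericyte markers that rose, by 1.91-fold. Their list median was 0.61 (camera adjusted p = 2.26e-05 in limma, and adjusted p = 0.26 with an estimated correlation). It was 0.38 without border array 3, which stood apart, and 0.20 with the title number as a fixed block.

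KRT77 was the 1 sweat gland gene of 13 that fell in border skin, 3.38-fold (log2 -1.76, SE 0.38), and the list of sweat glands did not pass (median -0.06, camera adjusted p = 0.718 in limma, and 0.42 with adjusted p = 0.197 with the title number as a fixed block). KRT31 fell by 0.68 on the log2 scale (SE 0.15), while the hair follicle list did not pass (median -0.27, camera adjusted p = 0.228 in limma). No gene of the sebaceous gland, basal keratinocyte or proliferation lists passed, while with the title number as a random block 1 and 2 of the first 2 lists fell and 1 of the last rose. These 3 lists had medians of -0.47, -0.27 and 0.20 (camera adjusted p = 0.00318, 0.00156 and 0.00301 in limma, and adjusted p = 0.405, 0.361 and 0.617 with an estimated correlation). With the title number as a fixed block the list of sebaceous glands no longer passed (median -0.23, adjusted p = 0.0903 in limma). Without unaffected array 4 its median was -0.19 (adjusted p = 0.0202 in limma). Under the fixed block basal keratinocytes had a median of -0.42, and the proliferation list did not pass without border array 7 (0.13, adjusted p = 0.0559 in limma). Among 25 ribosomal protein genes RPS3 and RPL3 fell by 0.28 and 0.21 on the log2 scale (SE 0.07 and 0.06; 9 fell adjusted over the list alone). Their median was -0.16 (camera adjusted p = 1.14e-07 in limma, and adjusted p = 0.0927 with an estimated correlation). The other large falls were UGT3A2, a glycosyltransferase gene, at a log2 change of -1.70 (SE 0.35), the cortisol-activating enzyme gene HSD11B1 at -1.25 (SE 0.30), and the pigment-switching gene ASIP at -1.15 (SE 0.23). They also included the glutathione transferase gene GSTM5 at -1.07 (SE 0.26), ELANE at -1.71 (SE 0.47), and MAPT, the tau gene, at -0.93 (SE 0.25). UGT3A2 and ASIP were each detected on 4 of 8 border arrays. The lists of Wnt pathway genes, fibroblasts, adipocytes, differentiating and inflamed keratinocytes, melanocytes, nerve, skeletal muscle, red blood cells, immediate early genes, heat shock genes and oxidative phosphorylation did not pass. With the title number as a fixed block, fibroblasts (median 0.13, adjusted p = 0.0347) and differentiating keratinocytes (median -0.30, adjusted p = 0.00489) did pass in limma, the latter also with it as a random block (adjusted p = 0.0405).

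In the limma fit 432 genes differed between border and unaffected skin, with 336 higher and 96 lower, of which 143 and 7 changed at least 2-fold. With the title number as a fixed block no gene passed in limma (smallest adjusted p = 0.062, and 3301 genes at an unadjusted p under 0.05). That block was fitted to all 30 arrays. Its estimate thus draws on the 5 pairs and also on numbers that link border or unaffected arrays to sclerotic ones. With a random block 1096 passed (720 higher, 376 lower). The count was 121 without filtering dim probes, 1666 with array weights, 233 with only numbers present in both groups and 1230 without the 2 arrays in doubt. Median scaling moved the share higher from 77.8% to 96.7%. With the stretch of the deposited order as a block it was 751, within the first 12 arrays 188, and within the last 18 arrays 0, where 1420 genes had an unadjusted p under 0.05 in limma. Leaving out 1 array at a time gave 0 (without border array 5 or 8) to 1190 (without unaffected array 9), a change of over 1.5 times for 16 of the 30 arrays.

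**Figure D3:**
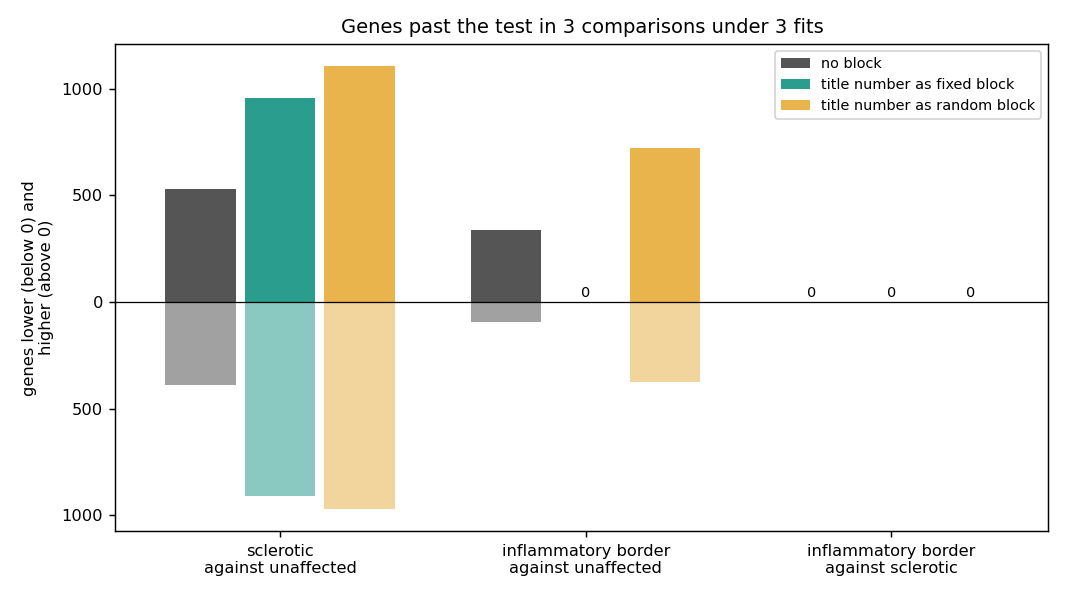
Number of genes (y axis, higher above 0 and lower below 0) with an adjusted p under 0.05 in limma in 3 comparisons (x axis) without a block, with the title number as a fixed block and with it as a random block. For border against unaffected skin the 3 fits gave 432, 0 and 1096 genes, and for border against sclerotic skin each gave 0.

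Border skin was then compared with sclerotic skin, which tests whether the lesional regions differ from unaffected skin by unequal amounts. Sweat gland genes were higher in border skin (n = 8) than in sclerotic skin (n = 12) as a list, and TGF-beta-responsive, basal keratinocyte and inflamed keratinocyte genes were lower, but no single gene passed over all genes. With an estimated correlation none of these lists passed in limma (adjusted p = 0.344, 0.697, 0.344 and 0.815 in that order). The median log2 difference of the 13 sweat gland genes was 1.14, with 10 higher adjusted over the list alone (camera adjusted p = 3.82e-13 in limma, and adjusted p = 0.344 with an estimated correlation). Of these, DCD stood 21.1-fold higher (log2 4.40, SE 1.22) and PIP 15.3-fold higher (log2 3.93, SE 1.07) in border skin, each higher in 5 of 6 number-matched pairs, with adjusted p = 0.964 over all genes in limma. Within the first 12 arrays of the deposited order the difference of the sweat gland list was -0.02, and within the last 18 it was 2.04. Border array 3 stood apart, with a sweat gland list level of -2.34 against 0.42 to 1.77 on the other border arrays.

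The TGF-beta-responsive list was lower in border than in sclerotic skin (median -0.25, camera adjusted p = 0.000888 in limma, and adjusted p = 0.697 with an estimated correlation). The median was -0.16 without border array 7, and THBS1 had a log2 difference of -0.94 (SE 0.36). Basal keratinocyte genes (median -0.31, 3 lower adjusted over the list alone, camera adjusted p = 1.15e-06 in limma, and adjusted p = 0.344 with an estimated correlation) included the epithelial transcription factor TP63 at -0.41 (SE 0.14) and the cadherin CDH3 at -0.84 (SE 0.29). Inflamed keratinocyte genes (median -0.73, camera adjusted p = 0.00161 in limma, and adjusted p = 0.815 with an estimated correlation) included S100A7, psoriasin, at -1.86 (SE 0.75) and S100A8 at -1.45 (SE 0.91). Their median was -0.46 without sclerotic array 9. With a fixed block for the title number the medians of basal and inflamed keratinocytes were -0.49 and -1.32.

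The lists of melanocytes (median -0.35, camera adjusted p = 0.0295), immediate early genes (-0.25, camera adjusted p = 0.00562) and ribosomal proteins (-0.07, camera adjusted p = 0.0028) were also lower in limma, with adjusted p = 0.815, 0.815 and 0.697 with an estimated correlation. The melanocyte call ended in limma with the stretch of the deposited order as a block (adjusted p = 0.12), and without the 2 arrays in doubt under a random block (adjusted p = 0.0977). It also ended without border array 1, 5 or 6 (medians -0.32, -0.23 and -0.23, adjusted p = 0.0684, 0.205 and 0.27 in limma) and without sclerotic array 5, 6, 11 or 12 (adjusted p = 0.0863, 0.123, 0.13 and 0.0686). That of immediate early genes ended without sclerotic array 2 (-0.21, adjusted p = 0.209 in limma). The lists of fibroblasts (median 0.25, camera adjusted p = 0.00562), endothelium (0.13, camera adjusted p = 0.00419), interferon-gamma-induced genes (0.21, camera adjusted p = 0.00986) and macrophages and monocytes (0.21, camera adjusted p = 0.0295) were higher in limma, with adjusted p = 0.815, 0.697, 0.85 and 0.85 with an estimated correlation. Under the fixed block their medians were 0.48, 0.23, 0.34 and 0.33. The fibroblast call ended without sclerotic array 9 (0.16, adjusted p = 0.0681 in limma), and its median was 0.16 without border array 8. The interferon-gamma call ended without sclerotic array 4 (0.11, adjusted p = 0.209 in limma) and without border array 6 or 8 (0.13 and 0.15, adjusted p = 0.103 and 0.0895). The macrophage call ended without border array 1, 2, 5 or 8 (adjusted p = 0.0684, 0.0731, 0.205 and 0.179 in limma, with a median of 0.13 without array 5), and its median was 0.35 without border array 7. It ended too without sclerotic array 2, 4, 6, 8, 11 or 12 (adjusted p = 0.0664, 0.163, 0.163, 0.0807, 0.13 and 0.0865 in limma, with a median of 0.12 without array 6), and without the 2 arrays in doubt under a random block (adjusted p = 0.0977). Genes of the list smooth muscle and pericytes were higher (median 0.24, camera adjusted p = 0.00914 in limma, and adjusted p = 0.815 with an estimated correlation), but with the title number as a fixed block the median of smooth muscle and pericytes was -0.06 (adjusted p = 0.462 in limma) and as a random block 0.16 (adjusted p = 0.0989 in limma). Nor did the list pass without border array 3 (0.05, adjusted p = 0.682 in limma) or sclerotic array 12 (0.17, adjusted p = 0.0686). The other 20 lists, those of T cells and of matrix proteins among them, did not pass in this comparison. Of these, 3 passed in limma with the title number as a fixed block, MHC class II (median 0.28, adjusted p = 0.0315), cytokines and chemokines (0.11, adjusted p = 0.0405) and adipocytes (0.23, adjusted p = 0.0207).

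No gene passed between border and sclerotic skin in limma (smallest adjusted p = 0.964), and 821 had an unadjusted p under 0.05. Among the genes with the smallest p were DENND2A, ROBO3 and STK32B, at log2 differences of 1.24 (SE 0.28), 0.51 (SE 0.13) and 0.55 (SE 0.15). In the other direction they included TRIM51 and S1PR5 at -0.53 (SE 0.13) and -0.68 (SE 0.18). The count was 0 under every alternative that was run. In simulated data with the same arrays, 98% of genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered for this comparison. DCD and PIP, with standard errors of 1.22 and 1.07, did not pass at larger differences, so that share does not hold for genes with such a spread. DENND2A, at 1.24 with a smaller standard error of 0.28, did not pass either. The simulated genes varied independently and 100 were changed at each size, which eases the adjustment of p-values. The share recovered therefore does not give the power of this comparison.

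Both lesional regions together, weighted equally, were finally compared with unaffected skin. In limma 1281 genes differed (adjusted p under 0.05), with 813 higher and 468 lower, of which 183 and 39 changed at least 2-fold. Under median scaling 1325 were higher and 118 lower. The count was 2358 with the title number as a random block, 2231 with array weights, 816 with only the numbers that had an unaffected array, and 2278 without the 2 arrays in doubt. It was 1598 with the stretch of the deposited order as a block, 617 within the first 12 arrays and 0 within the last 18, where 1906 genes had an unadjusted p under 0.05 in limma. Leaving out unaffected array 7 gave 794, unaffected array 6 gave 816 and unaffected array 9 gave 2122.

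The changes of sclerotic and of border skin against the same unaffected arrays were set side by side over all 16954 genes. Of the genes called, 253 were higher in both regions and 43 lower in both, among them CXCL9, CD8A and TNC higher and WIF1 and KRT77 lower, and none was called in opposite directions. Independent lists of these sizes would share 10.5 and 2.2 genes, a figure that leaves the shared controls out of account. Simulated unchanged groups against the same controls shared 0 and 0.01 on average. No gene was changed in those groups, so a count near 0 was fixed beforehand. It does not show how far shared controls raise the overlap. With the unaffected arrays split into 5 and 5, so that the comparisons shared no control, 0.07 and 0.09 genes were shared on average. How many genes passed in each comparison with 5 controls was not kept. These counts therefore do not show how much of the overlap comes from shared controls. The correlation of the fold changes over genes, which are not independent replicates, was 0.823, against a mean of 0.491 (0.078 to 0.842) in the simulation and 0.65 (0.476 to 0.766) with split controls. The covariance was 0.075, against 0.013 in the simulation and 0.064 with split controls, a difference from the simulation of 0.062. Border and sclerotic arrays also share title numbers, which adds covariance that neither figure removes.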

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

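The tests of exchanged labels and of biopsy depth and dilution, and the fits by position in the deposited table, were chosen only after the result each addresses was seen. Each array was set against the others of its group for the genes named and for the gene lists, in the groups of 8 and 10 arrays, and called apart where its gap to the nearest other array was large for the range of the group by Dixon's criterion. This held for 22 of 172 gene and group pairs and 13 of 64 list and group pairs, where chance gives about 1 in 20. Genes and lists that move together are not independent, and 17 of these flags fell on unaffected array 9 and 9 on border array 3. The excess over 1 in 20 was therefore not tested.

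On inflammatory border array 3, sweat gland genes were far below the other border arrays, with DCD at 6.39 (log2 level, others 13.34 to 14.50), PIP at 5.0 (11.13 to 13.52), SCGB2A2 at 6.08 (11.98 to 13.93) and SCGB1D2 at 5.06 (9.88 to 12.34), and a sweat gland list level of -2.34 (0.42 to 1.77). The same array was the highest for COL11A1 at 9.40 (4.83 to 5.93), TAGLN at 14.16 (11.93 to 12.78), the smooth muscle and pericyte list at 1.43 (-0.30 to 0.49) and the inflamed keratinocyte list at 1.89 (-0.93 to 0.36). Border array 7 was the lowest for CD74 at 12.79 (13.30 to 13.75) and for the matrix list at -1.37 (-0.24 to 0.69), and the highest for the basal keratinocyte list at 0.27 (-0.48 to -0.13). Border array 6 was the highest for WIF1 at 6.57 (4.99 to 5.49) and border array 2 for the hair follicle list at 1.18 (-0.55 to 0.26).

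On unaffected array 9, interferon-induced genes were above the other 9 unaffected arrays, with UBD at 10.38 (others 5.51 to 7.76), IRF1 at 11.19 (8.13 to 9.55), EPSTI1 at 10.21 (6.45 to 8.09) and OAS2 at 9.94 (7.32 to 8.34). So were HLA-DPA1 at 13.74 (11.15 to 12.39), HLA-DMB at 12.68 (10.03 to 11.37), CCL2 at 11.11 (8.06 to 9.33), CCL8 at 10.35 (6.43 to 8.0), IL15 at 7.85 (6.31 to 7.06), FCGR1A at 7.42 (4.82 to 5.14) and ADAMDEC1 at 9.66 (5.05 to 6.33), as well as SULF1 at 9.90 (6.05 to 8.04), while CACNA1H was the lowest at 6.42 (8.69 to 10.24). Its list levels were the highest for interferon-gamma-induced genes at 1.35 (-1.52 to -0.32), type I interferon-induced genes at 0.60 (-0.97 to -0.35), cytokines and chemokines at 0.70 (-0.65 to -0.01) and TGF-beta-responsive genes at 0.32 (-0.88 to -0.30). Unaffected array 7 was the lowest for CXCL12 at 10.03 (11.11 to 11.69) and the matrix list at -1.20 (-0.46 to 0.27), unaffected array 5 the highest for the hair follicle list at 1.33 (-0.49 to 0.34), and unaffected array 4 for the sebaceous gland list at 2.68 (-0.52 to 0.91).

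In 12 lists the change against unaffected skin differed between border and sclerotic skin in camera at the preset correlation, and in none with an estimated correlation (smallest adjusted p = 0.344 in limma) or by fry. The value given for each list is the median over its members of the log2 difference, border minus sclerotic. It was 1.142 for sweat glands, 0.253 for fibroblasts, 0.237 for smooth muscle and pericytes and 0.214 for interferon-gamma-induced genes. For macrophages and monocytes it was 0.207 and for endothelium 0.132. For inflamed keratinocytes it was -0.733, for melanocytes -0.346 and for basal keratinocytes -0.308. It was -0.253 for immediate early genes, -0.252 for TGF-beta-responsive genes and -0.066 for ribosomal proteins.

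For 1 of the 10 numbers with both a sclerotic and an unaffected array, the arrays lay the other way round along the lesional axis. A lesional score from genes chosen without the number in question put 4 of 25 arrays nearer the other class, among them both of this number (2), which restates the pattern and so does not decide whether the 2 arrays of the pair carry each other's labels. Over 30 genes whose level varies between people through inherited variants, the worse of the ranks at which this pair's arrays found each other was 10 of 29, against 1 to 4 for the 20 other pairs. This met the rule set beforehand for an array from a person of another number. Pairs of arrays with different numbers were not ranked, so how often such pairs give a rank of 10 is not known. An exchange within 1 person would leave the inherited variants alike, but the ranks used deviations from the mean of the labelled group. Exchanged labels would shift these deviations in opposite directions for genes that differ between the groups. How far this could lower the rank was not tested, so the value of 10 does not decide against an exchange. A difference that ran the other way in this person's skin was not tested either. Both technical accounts stay open.

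Sweat gland genes were lower on sclerotic arrays than on unaffected arrays (median log2 change -1.41), which a shallower biopsy or dilution by infiltrating cells could give. Fat cell genes, from below the glands, had a median change of -0.026 (bootstrap SE 0.42, 17 genes), above -0.706, which is 0.5 of the sweat gland change, by less than 2 standard errors, so this speaks only weakly against shallower biopsies; the margin asked for was set at 1 standard error after the value had been seen. For dilution, the median over 5 lists of other resident cells was -0.026 (SE 0.125), which is the value of the fat cell list itself. The other lists had medians of 0.056 for basal keratinocytes, 0.041 for melanocytes, -0.192 for hair follicles and -0.269 for fibroblasts. All lay above -0.706, which argues against dilution as the whole cause. Those of hair follicles and fibroblasts were negative, so a share from dilution stays open. The median change of sweat glands was -0.814 in the first 12 arrays of the deposited order and -1.589 in the last 18, so its size moved with position. A loss of glands in sclerotic skin remains a hypothesis beside uneven sampling of glands.

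The first 12 arrays of the deposited order stood apart from the other 18 on the third principal component (9% of the variance), which was below 0 for 11 of the 12 and above 0 for 18 of 18. In limma 1338 genes differed between stretches of 12, 12 and 6 arrays, and 1 of 100 assignments of whole title numbers to stretches, the real one, gave as many (highest other 499, median 19), so chance differences between people are argued against and a processing batch in file order would give this. Only 1 number had arrays in more than 1 stretch, and no label names a batch, so whatever else differed between the people of each stretch stays open, and no biological explanation was tested.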

How the results depend on the processing

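The fits without 2 arrays, by stretch and within stretches of the deposited order, and the omission of single arrays from the list tests were chosen only after the data were seen, and the slide as a block was not run because no slide is given. Counts are for sclerotic, border and both lesional regions against unaffected skin (919, 432 and 1281 as reported). With the title number as a fixed replicate block they were 1866, 0 and 1577 (0 in limma, with 3301 genes at an unadjusted p under 0.05), and with it as a random block 2077, 1096 and 2358. Without filtering dim probes the first and second were 566 and 121, with array weights the second and last were 1666 and 2231, and with only numbers in both groups they were 433, 233 and 816. Without the 2 samples whose titles carry an unexplained abbreviation they were 713, 341 and 1097. Without the 2 arrays in doubt they were 1903, 1230 and 2278, and with a random block as well 3334, 2204 and 3623. With the stretch as a block border against unaffected skin gave 751. Within the first 12 arrays the counts were 194, 188 and 617 and within the last 18 they were 0, 0 and 0 (smallest adjusted p = 0.0827, 0.535 and 0.129 in limma, and 1989, 1420 and 1906 genes at an unadjusted p under 0.05). Border against sclerotic skin gave 0 throughout, and the counts stayed within 1.5 times under the other alternatives. The cause of these shifts was not tested, and the larger of the 2 stretches gave the lower counts. Unaffected array 9 lies in the last 18, and the counts over all other arrays without it were 1679, 1190 and 2122. The last 18 arrays were not fitted without it.

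Leaving out 1 array at a time gave 530 to 1679 genes for sclerotic against unaffected skin, 0 to 1190 for border, 794 to 2122 for both regions and 0 to 0 for border against sclerotic skin. For sclerotic skin the arrays behind changes of over 1.5 times were sclerotic 10 (530) and 9 (603) and unaffected 4 (534), 6 (591) and 9 (1679), and for both regions unaffected 7 (794), 6 (816) and 9 (2122). For border skin they were unaffected 1 (166), 2 (275), 3 (81), 4 (95), 6 (91), 7 (1), 8 (245) and 9 (1190), and border 1 (191), 2 (285), 3 (259), 4 (199), 5 (0), 6 (89), 7 (956) and 8 (0).

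Of 124 results for named genes past the test, none changed sign. Of the 73 in sclerotic and 51 in border skin, the numbers that no longer passed were 0 and 51 with the fixed block, 0 and 0 with the random block, 16 and 23 without filtering dim probes, and 30 and 26 with only shared numbers. They were 9 and 7 without the 2 samples whose abbreviation is unexplained, 9 and 1 with only the 2 groups compared, 52 and 31 within the first 12 arrays, and 73 and 51 within the last 18. Each other alternative lost at most 5 and 5, the omission of single arrays aside, but only 49 and 37 were tested with probes detected on all arrays.

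Of the list results (20 in sclerotic skin, 18 in border skin and 12 between the regions), all lost their call with an estimated correlation, and 11, 8 and 0 kept it under fry. Median scaling ended or turned 6, 2 and 0, namely cytokines, matrix, endothelium, smooth muscle, inflamed keratinocytes and oxidative phosphorylation in sclerotic skin and dendritic cells and matrix in border skin. Probes detected on all arrays, with 19, 17 and 12 results tested, ended 2 (sebaceous glands and inflamed keratinocytes), 3 (dendritic cells, mast cells and sebaceous glands) and 3 (endothelium, inflamed keratinocytes and melanocytes). The last 18 arrays ended 4 (cytokines, matrix, sebaceous glands and differentiating keratinocytes), 5 (dendritic cells, mast cells, matrix, TGF-beta-responsive genes and sebaceous glands) and 2 (macrophages and smooth muscle). The first 12 ended or turned 2 (smooth muscle and oxidative phosphorylation), 2 (dendritic cells and proliferation) and 10. Cyclic loess ended 1, 1 and 1, only shared numbers ended or turned 0, 1 and 2, and leaving out the 2 samples with the abbreviation ended 1, 0 and 1 (differentiating keratinocytes in sclerotic skin and macrophages between the regions). Without the 2 arrays in doubt the numbers were 1, 0 and 2, and with a random block as well 0, 0 and 3. The random block, the most variable probe, only the 2 groups compared and the stricter filter each ended 1, and the rest none except as given below.

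The lists whose test turned direction were smooth muscle and pericytes between border and sclerotic skin (-0.06 with the fixed replicate block, -0.049 with only shared numbers), oxidative phosphorylation in sclerotic skin (0.092 under median scaling), and, within the first 12 arrays, sweat glands (-0.016) and melanocytes (-0.019) between border and sclerotic skin. The median alone turned sign, while the test kept its direction, for ribosomal proteins in sclerotic skin (0.017 under median scaling), dendritic and Langerhans cells in border skin (-0.165 with probes detected on all arrays) and collagens and other matrix proteins in sclerotic skin (-0.081 within the last 18 arrays).

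The fixed block ended 2 list calls, that of smooth muscle and pericytes and that of sebaceous glands in border skin (adjusted p = 0.0903 in limma), and brought 7. These were dendritic and Langerhans cells (adjusted p = 0.0355) and immediate early genes (0.03) in sclerotic skin, fibroblasts (0.0347) and differentiating keratinocytes (0.00489) in border skin, and MHC class II (0.0315), cytokines and chemokines (0.0405) and adipocytes (0.0207) between the regions, in limma.

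Leaving out 1 array ended the call of 3 of 20 lists in sclerotic skin, 3 of 18 in border skin and 6 of 12 between the regions, and turned none. Each is given in the results with the array and its value. The stretch as a block ended the call of melanocytes between the regions (adjusted p = 0.12 in limma) and brought that of MHC class II (adjusted p = 0.026). Between 44.2% and 49.4% of probes lay above background per array, and changes of genes near it are understated.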

Other observations

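The tests here were not part of the design, and the correlations between lists were chosen after the group comparisons were seen and before the correlations were computed. Among the 12 sclerotic arrays, keratinocyte and blood genes varied widely. The level of the inflamed keratinocyte list ran from -1.42 to 3.06 (SD 1.41, n = 12), against -1.14 to 0.01 (SD 0.33, n = 10) on unaffected arrays. Haemoglobins and other red blood cell genes ran from -2.56 to 2.59 (SD 1.56, n = 12) on sclerotic and from -1.19 to 1.51 (SD 0.95, n = 10) on unaffected arrays. B and plasma cell genes ran from -0.77 to 2.98 (SD 0.96, n = 12) on sclerotic and from -0.84 to -0.27 (SD 0.21, n = 10) on unaffected arrays. On border arrays (n = 8) the SD was 0.956 for inflamed keratinocyte, 1.47 for red blood cell and 0.735 for B and plasma cell genes. The highest B cell level on sclerotic arrays was that of array 8, and the next was 1.07 on array 5. These spreads were not tested against each other.

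TGF-beta-responsive and matrix genes, which share no member, moved together over the 12 sclerotic arrays (Pearson's r = 0.745, permutation p = 0.00557, adjusted p = 0.0167 by Benjamini-Hochberg over 3 relations, and Spearman's rho = 0.755, permutation p = 0.00607, adjusted p = 0.0182). Without the 2 arrays farthest from the median TGF-beta level r was 0.67, and after removing the mean of each stretch of the deposited order it was 0.833 (permutation p = 0.00095). No stretch held more than 5 sclerotic arrays, so r was not computed within 1. Among 1000 pairs of random lists 10 had an r as high, so the relation is consistent with a shared programme of these genes, as a hypothesis, and a shared cell type, such as a varying share of fibroblasts, was not excluded. Interferon-gamma-induced genes showed no such relation, with r = -0.371 with matrix genes (permutation p = 0.233, adjusted p = 0.35 by Benjamini-Hochberg, rho = -0.196 with permutation p = 0.545 and adjusted p = 0.749, r = 0.247 without the 2 farthest arrays) and r = -0.19 with TGF-beta-responsive genes (permutation p = 0.561, adjusted p = 0.561 by Benjamini-Hochberg, rho = -0.105 with permutation p = 0.749 and adjusted p = 0.749, r = 0.093 without the 2 farthest arrays). With 12 arrays these do not show that the lists vary independently.

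Other splits of the same arrays were used to ask how often chance gives as many genes in limma. For sclerotic against unaffected skin 1 of 100 splits, the real one, gave 919 or more (highest other 320). So did 1 of 100 that exchanged regions within title numbers (highest other 70). This argues against chance but cannot exclude it, since 1 of 100 is the smallest share these splits can give. For border against unaffected skin 2 of 100 splits gave 432 or more, and the other of these gave 915. A random grouping of these arrays can thus part more genes than the real one, and what set its groups apart was not tested. Within title numbers 1 of 32 splits, the real one, did so (highest other 0), so both shares lie under 5%, although 1 other split gave more genes than the real one. The splits within title numbers exchanged only the 5 number-matched pairs, and the other arrays kept their labels. A share of 1 of 32 is the smallest they can give, so they cannot exclude chance. For both lesional regions 1 of 100 splits gave 1281 or more (highest other 3), and 1 of 100 within title numbers (highest other 583). This argues against chance with the same limit. For border against sclerotic skin, with 0 genes in limma (821 at an unadjusted p under 0.05), every split gives at least as many by construction, 100 of 100 and 64 of 64 within title numbers (highest other 154 and 0), so the splits decide nothing there. Splits within title numbers exchange labels only inside a number and keep the differences between numbers, whereas the others mix them.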
